A study of Mus musculus with 4 samples.

How the data were processed

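RNA of the embryonic mouse cortex was sequenced in 4 libraries, 2 of wild-type and 2 of Trpm2-knockout C57BL/6 mice. All 4 came from warmed pregnancies, per the labels, with warmth given between embryonic days 14 and 16. The labels number the libraries 1 and 2 within each genotype. No label says that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. The labels do not say either whether a shared number marks a litter or a batch, or which part of Trpm2 the knockout lacks.

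The authors deposited 1 table for each knockout and wild-type library of the same number, called pair 1 and pair 2 here. Each table holds whole read counts per gene for both libraries, as deposited and without normalization. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 without giving their roles, and name the build mm9. Gene positions in the tables were compared with GENCODE M21 on GRCm38, and 22713 of 22715 matched gene identifiers (99.99%) overlapped the same gene there. Coordinates are therefore given as in the deposited tables and read as GRCm38. The deposited normalized columns are CPM values (reads scaled by the library total) in which the authors entered a count of 0 as 0.5 read. The deposited fold column is the ratio of knockout over wild type of these CPM values, and the deposited log2 column is its logarithm. Each gene also has a deposited p-value and an adjusted p-value from the authors, whose test is named in none of the sources used here, and the adjusted value lies below the unadjusted p for some genes. These p-values compare 1 knockout library with 1 wild-type library, so they cannot measure the spread between replicates. The column headers call the wild-type libraries controls, and every per-sample column was assigned to a library by its genotype and number, with 0 left over.

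The table of pair 1 listed 21319 genes and that of pair 2 listed 21391, of which 19931 were in both. Genes listed in 1 table only numbered 1388 and 1460, and held 0.0162% and 0.024% of the reads of their libraries. The smallest listed total over a pair was 2 reads, so a gene missing from a table was entered as 0 in that pair. The joined table had 22779 genes. Listed counts summed to 19074785 and 18018596 in wild type 1 and 2 and to 17852876 and 17637406 in knockout 1 and 2.

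Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing the default filterByExpr criteria were kept, libraries were scaled by TMM, and the genotypes were compared by a quasi-likelihood F test without any further term. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of F. CPM per library were scaled by TMM, and log2 ratios within a pair were taken from log-CPM with a prior count of 2. Means are given with the standard deviation (SD) over the 2 libraries of a genotype. Proportions carry Wilson intervals at the 95% level. These intervals and the floor of 3 counts per library used for genes at 0 cover counting error only. With 2 libraries against 2, the smallest two-sided exact permutation p that a single gene can reach is 0.33, so no such test was made.

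Before the data were examined, 27 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. The lists covered TRP channels, SP and KLF factors, Wnt targets, Wnt ligands and receptors, the heat shock, oxidative stress, unfolded protein and p53 responses and immediate early genes. They also covered radial glia, intermediate progenitors, proliferation, pan-neuronal, deep-layer and upper-layer genes, interneurons, and markers of the striatum, thalamus, cortical hem with Cajal-Retzius cells, choroid plexus, erythroid cells, vessels, microglia, meninges, and the oligodendrocyte and astrocyte lineage. Trpm2 with its neighbours on chromosome 10, and sex-linked genes, completed them. Lists with at least 3 tested members, 26 in all, were compared with the remaining genes by camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and by the rotation test fry. The p-values were adjusted over the 26 lists. Individual members were also adjusted over the list alone.

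The named genes were Trpm2 and Sp5. Added to these were genes past the threshold with a mean CPM of at least 1 and non-overlapping genotypes, up to 15 per direction. Where fewer than 10 per direction passed, non-overlapping genes with a mean CPM of at least 5 and the largest absolute log2 fold changes filled the places, described as not passing. Up to 4 members of a list with the smallest p, and all sex markers detected, could also be named.

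The same comparison was repeated with RLE, upper-quartile and library-size scaling, without a filter, with a filter of CPM of at least 1 in at least 2 libraries, with the replicate number as a block, with DESeq2 1.42.0 and with limma-voom. It was also repeated without erythroid genes, with the authors' threshold of p under 0.05 and absolute log2 fold change over 1, with an adjusted p and the same fold, and without each library in turn. In the last case the lone library of a genotype was assumed to vary like those of the other. Further alternatives were chosen after seeing the data: a GC correction, which removed each library's trend on transcript GC content by lowess with a span of 0.3, the same together with the block, a GC correction of the pair ratios, and the erythroid list without Hbb-bt. A GC content was found for 16054 of the tested genes (99.8%). Lists of epidermal and muscle genes were also added then. Near-identical copies were searched among annotated transcripts with BLAST 2.17.0, as 95% identity over 200 bases. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for joining, resampling and plots.

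The scheme was tested on simulated counts with 200 changed genes among 15812 to 15841 tested. With the spread within pairs, 77% of genes changed 2-fold and 98.5% of those changed 4-fold were recovered. With the spread between libraries of a genotype, these shares were 54.5% and 93.5%. False calls numbered between 2 and 5. Each simulated gene had the spread typical of its expression level. The simulated libraries were drawn independently, with no deviation shared by libraries of the same number and no trend on GC content. Recovery in the data may therefore be lower.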

Results

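Transcripts of the embryonic mouse cortex were counted in 2 wild-type and 2 Trpm2-knockout libraries, all from pregnancies kept warm between embryonic days 14 and 16. Trpm2 encodes a calcium-permeable cation channel that opens in response to heat, ADP-ribose and oxidative stress. The comparison asked which transcripts of the heat-exposed cortex differ when this channel is missing, with the Wnt-responsive transcription factor Sp5 as the gene the study's title singles out. Counted reads numbered 19074785 in wild type 1, 18018596 in wild type 2, 17852876 in knockout 1 and 17637406 in knockout 2. Between 21234 and 21306 genes had at least 1 read. Mitochondrial genes took 3.46% and 2.38% of the reads in wild type 1 and 2, and 3.38% and 2.81% in knockout 1 and 2. The 10 most abundant genes took 5.24% to 5.82%. Libraries without warming were not analysed here, so the values describe genotype within warmth and not the response to warmth.

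Trpm2 reads were counted at similar levels in both genotypes, and Sp5 was a weakly expressed gene whose knockout values lay on both sides of a wild-type value. Neither gene passed the test. Trpm2 (ENSMUSG00000009292, chromosome 10, 77907722 to 77970563, minus strand) had 126 and 159 reads in wild type 1 and 2, and 94 and 127 reads in the libraries labelled knockout 1 and 2. These were 7.7 ± 1.41 CPM (counts scaled by library size and TMM) in wild type and 6.23 ± 1.21 CPM in the knockout (SD, n = 2), a log2 fold change of −0.31 with an SE of 0.26 (edgeR, adjusted p = 1). The counts cover the whole gene and the deleted part is not given, so they do not check the genotype of a library. The Trpm2 ratio was −0.31 in pair 1 and −0.29 in pair 2 on the log2 scale. Its log2 fold change was −0.12 without knockout 1, −0.11 without wild type 2, −0.46 without wild type 1 and −0.52 without knockout 2. Sp5 (ENSMUSG00000075304, chromosome 2, 70474923 to 70477729, plus strand) encodes a zinc-finger repressor that is switched on directly by Wnt/beta-catenin signalling. It had 33 and 50 reads in wild type 1 and 2, and 12 and 39 reads in knockout 1 and 2. Mean Sp5 expression was 2.25 ± 0.694 CPM in wild type and 1.43 ± 1.05 CPM in the knockout (SD, n = 2). The log2 fold change was −0.64 with an SE of 0.54 (edgeR, adjusted p = 1), from ratios of −1.23 in pair 1 and −0.32 in pair 2. Knockout 1 set this value, since the log2 fold change was −0.04 without knockout 1 and −1.7 without knockout 2. It was −0.91 without wild type 1 and −0.29 without wild type 2, and none of these passed the test. In the deposited tables the authors gave Sp5 a log2 fold change of −1.36 in pair 1 (their adjusted p 0.0144) and −0.33 in pair 2 (their adjusted p 0.36). Their values for Trpm2 were −0.33 (adjusted p 0.199) and −0.29 (adjusted p 0.156). These p-values of the authors compare 1 library with 1 and do not measure replication.

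**Figure D1:**
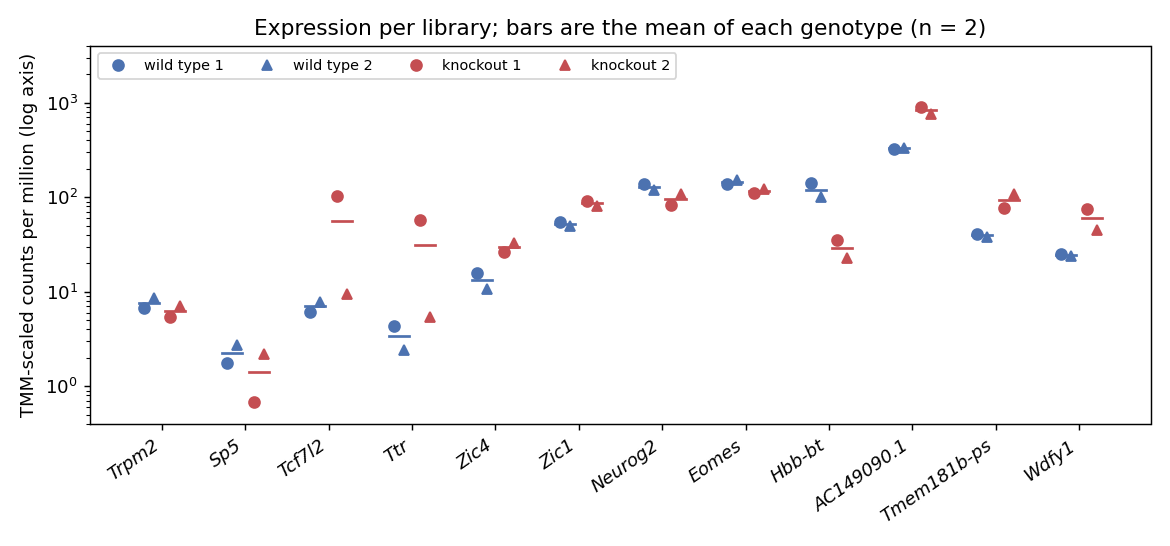
TMM-scaled CPM (log axis) of 12 genes in each library, with wild type in blue, knockout in red, circles for replicate 1, triangles for replicate 2 and bars for the mean of each genotype (n = 2). Trpm2 lay between 5.37 and 8.7 CPM in all 4 libraries, Tcf7l2 reached 103.3 CPM in knockout 1 alone, and Hbb-bt was lower in both knockout libraries than in either wild-type library.

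Across the genome, no gene passed the edgeR test with genotype as its only term, although a handful of genes differed by a similar factor in both pairs. Markers of the thalamus and choroid plexus were among the largest differences, and most of their excess came from knockout 1. Of 16089 genes tested, 0 had an adjusted p under 0.05 in the edgeR fit with genotype alone, and the smallest was 0.415. An unadjusted p under 0.05 was found for 195 genes, 118 higher and 77 lower in the knockout, where 5% of the tested genes would be 804. limma-voom also called 0 genes, with 182 at an unadjusted p under 0.05, and DESeq2 called 6. Fits without each library in turn leave 1 genotype with a single library, whose spread is taken from the other genotype. Their p-values therefore do not measure replication. Fold changes and list calls from them are given only to show which library a result rests on. The epidermal genes Krt77, Krt14, Calm4, Krtdap, Dmkn and Krt5, chosen for mention after their values were seen, were all highest in wild type 2. The genotypes did not overlap for 3971 genes (24.7%), against 33.3% by chance for 2 interchangeable libraries against 2. The 804 rests on the same assumption. Libraries of the same number deviated partly alike across genes, which can lower both counts. Neither shortfall therefore shows that the genotypes differ less than by chance.

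Among genes with a mean CPM of at least 5 and the largest non-overlapping excess in the knockout, none of which passed the edgeR test, several are known from the thalamus or the choroid plexus. Ttr (ENSMUSG00000061808, chromosome 18, 20665250 to 20674324), the thyroid-hormone carrier secreted by the choroid plexus, had 4.36 and 2.41 CPM in wild type 1 and 2, and 56.9 and 5.36 CPM in knockout 1 and 2. Its log2 fold change was 3.2 (SE 0.98, edgeR adjusted p = 1). It was 0.66 without knockout 1 and 4.07 without knockout 2. Tcf7l2 (ENSMUSG00000024985, chromosome 19, 55741810 to 55933654) encodes an HMG-box partner of beta-catenin and marks thalamic neurons. It had 7 ± 1.25 CPM in wild type and 56.4 ± 66.4 CPM in the knockout (SD, n = 2), with 103.3 CPM in knockout 1 and 9.43 CPM in knockout 2. The Tcf7l2 log2 fold change was 3.01 (SE 0.94), and became 0.43 without knockout 1 and 3.88 without knockout 2. The synaptotagmin Syt13 (log2 fold change 1.29, SE 0.45) and the axon-guidance ligand Ntng1 (1.11, SE 0.44), which is expressed in the thalamus, followed the same course. Their log2 fold changes were 0.39 and 0.2 without knockout 1, and 1.84 and 1.67 without knockout 2. Lhx8, a LIM-homeobox gene of the ventral forebrain, had 1.01 and 7.28 CPM in wild type 1 and 2, and 7.71 and 12.8 CPM in knockout 1 and 2 (log2 fold change 1.31, SE 0.73). Without knockout 1 its log2 fold change was 1.63, without wild type 1 it was 0.52 and without wild type 2 it was 3.33. Zic4 (ENSMUSG00000036972, chromosome 9, 91362413 to 91389348), a zinc-finger gene of the dorsal midline and diencephalon, was higher in both knockout libraries. It had 13.3 ± 3.74 CPM in wild type and 29.6 ± 4.42 CPM in the knockout (SD, n = 2), a log2 fold change of 1.16 (SE 0.24). Without knockout 1 it was 1.3.

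Among genes with a mean CPM of at least 5 and non-overlapping genotypes, the lower side was led by 1 adult globin transcript, and Mrps34, Fam177a and Cox5a had their lowest values in knockout 1. None of these genes passed the edgeR test. Hbb-bt (ENSMUSG00000073940), an adult beta-globin gene, had 120.7 ± 28.3 CPM in wild type and 28.9 ± 8.74 CPM in the knockout (SD, n = 2), a log2 fold change of −2.06 (SE 0.26, edgeR adjusted p = 0.564). The keratin gene Krt10, typical of differentiating epidermis, had 6.81 and 19.4 CPM in wild type 1 and 2, and 4.74 and 5.41 CPM in knockout 1 and 2. Its log2 fold change of −1.37 (SE 0.46) became −0.42 without wild type 2 and −1.47 without knockout 2. Mrps34, which encodes a protein of the small mitochondrial ribosome subunit, had 10.1 and 12 CPM in wild type 1 and 2, 1.2 CPM in knockout 1 and 8.98 CPM in knockout 2. Fam177a, of little-described function, had 6.76 and 7.34 CPM in wild type 1 and 2, 0.914 CPM in knockout 1 and 6.3 CPM in knockout 2. Cox5a, a subunit gene of cytochrome c oxidase, had 27.2 CPM in knockout 1 against 72 to 87.5 CPM in the other libraries. The log2 fold changes of these genes were −1.11 (SE 0.71), −0.96 (SE 0.69) and −0.7 (SE 0.4). Without knockout 1 they were −0.3, −0.16 and −0.17. Without knockout 2 they were −3.2, −2.94 and −1.57. Gas1, a cell-surface co-receptor for Sonic hedgehog, had 52.2 and 56.5 CPM in wild type 1 and 2, and 31.1 and 39.9 CPM in knockout 1 and 2 (log2 fold change −0.61, SE 0.17). Hopx, a radial-glia marker, had a log2 fold change of −0.68 (SE 0.31), and Dct, a melanin-pathway enzyme also made in cortical progenitors, −0.61 (SE 0.28). Hopx was at −0.31 without knockout 1 and −1.17 without knockout 2, and Dct at −0.26 without wild type 1. Fam71e1 (−0.66, SE 0.21) and Gm3164 (−0.68, SE 0.3, or −0.29 without wild type 1) completed the set.

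DESeq2 called 6 genes, all of which differed in the same direction in both pairs. The set joined globin, dynein and endosomal genes with pseudogenes and a poorly described protein-coding gene, and held no marker of a cortical cell type. AC149090.1 (ENSMUSG00000095041, scaffold JH584304.1, 52190 to 59690) had 330.3 ± 2.94 CPM in wild type and 831.9 ± 98.5 CPM in the knockout (SD, n = 2), with a DESeq2 log2 fold change of 1.34 (adjusted p = 2.96e-09). Hbb-bt (chromosome 7, 103812524 to 103813996) had −2.05 (adjusted p = 8.62e-09). Tmem181b-ps (chromosome 17, 6438524 to 6467022), a pseudogene of a transmembrane protein, had 39.6 ± 1.87 CPM in wild type and 93.6 ± 22.6 CPM in the knockout (SD, n = 2). Its DESeq2 log2 fold change was 1.25 (adjusted p = 0.000745). Dynlt1b (chromosome 17, 6430112 to 6436293), a dynein light-chain gene beside it, had 1.16 (adjusted p = 0.0438). Wdfy1 (chromosome 1, 79702262 to 79776143) encodes a protein of early endosomes, and its DESeq2 log2 fold change was 1.29 (adjusted p = 0.0362). With edgeR it was 0.85 without knockout 1, and not called. Gm28438 (chromosome 1, 24612775 to 24613119), named after its values were seen, had 0 reads in both wild-type libraries and 126 and 69 in knockout 1 and 2 (DESeq2 adjusted p = 1.67e-05). Against a floor of 3 counts per wild-type library it was at least 23.5-fold higher. With edgeR the other genes had log2 fold changes of 1.33 (AC149090.1, SE 0.15, adjusted p = 0.415), 1.24 (Tmem181b-ps, SE 0.2), 1.15 (Dynlt1b, SE 0.23) and 1.28 (Wdfy1, SE 0.26). Without knockout 1 the edgeR log2 fold changes were 1.21 (AC149090.1), 1.47 (Tmem181b-ps), 1.44 (Dynlt1b) and −2.41 (Hbb-bt). Without knockout 2 they were 1.45 (AC149090.1), 0.97 (Tmem181b-ps), 0.79 (Dynlt1b), 1.61 (Wdfy1) and −1.78 (Hbb-bt). A stretch nearly identical to another gene was found in 4 of the 5 of these genes with a searchable transcript, the exception being Wdfy1.

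In the fit to all 4 libraries, gene lists fixed beforehand showed markers of the diencephalon, choroid plexus, ventral forebrain and meninges higher in the knockout. Markers of cortical progenitors and erythroid cells were lower. However, the medians of pair 1 and pair 2 had opposite signs for the striatal (0.63 and −0.08), meningeal (0.65 and −0.14) and radial glia lists (−0.31 and 0.1). With camera at its preset correlation, 9 of 26 lists passed the threshold, 5 up and 4 down. With an estimated correlation 0 lists passed, and fry called 0 lists for either a common direction (smallest adjusted p = 0.836) or any change (smallest adjusted p = 0.854). In no list did a member pass when adjusted over all genes.

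Thalamic and diencephalic markers rose as a list (limma camera, adjusted p = 5.77e-08; adjusted p = 0.642 with an estimated correlation), with a median log2 fold change of 0.51 over 13 members. Of these, 8 were higher in both pairs, 1 was lower in both and 4 were opposite. The pair medians were 0.73 and 0.21, and without knockout 1 the list no longer passed (adjusted p = 0.0831). Zic4 and its neighbour Zic1, which act together in the dorsal midline, were the only members called when adjusted over the list alone (both adjusted p = 0.016). Zic1 had 52.3 ± 4.4 CPM in wild type and 86.2 ± 8.33 CPM in the knockout (SD, n = 2; log2 fold change 0.72, SE 0.16). Gbx2, which specifies thalamic neurons, had 5.31 CPM in knockout 1 and at most 1.67 CPM elsewhere (log2 fold change 2.14, SE 0.76). Without knockout 1 its log2 fold change was 1.08, and without knockout 2 it was 2.75. Of the 13 members, 10 had a mean of at least 1 CPM in the wild-type cortex and 4 were in another list.

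Choroid plexus markers rose too (adjusted p = 6.96e-08; adjusted p = 0.642 with an estimated correlation), with a median of 0.72 over 10 members and 9 higher in both pairs. The pair medians were 0.81 and 0.39. The direction held without each library in turn, and 0 members were called adjusted over the list alone (smallest 0.138). Otx2, a homeobox gene needed to form the choroid plexus, had 2.23 and 2.68 CPM in wild type 1 and 2, and 3.26 and 5.64 CPM in knockout 1 and 2 (log2 fold change 0.85, SE 0.34, or 0.41 without knockout 2). Clic6, a chloride-channel gene of that epithelium, had a log2 fold change of 1.25 (SE 0.56) that was 0.23 without knockout 1. The folate receptor gene Folr1 stood at 0.213 and 0.219 CPM in wild type 1 and 2, and at 0.571 and 0.558 CPM in knockout 1 and 2. These were 4 reads in each wild-type library and 10 in each knockout library. Folr1 reached the level of the expression filter in the knockout libraries only. Its place among the 9 members higher in both pairs therefore depended on that excess. Only 5 of the 10 members had a mean of at least 1 CPM in wild type.

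Striatal and ventral forebrain markers rose (adjusted p = 0.000605; adjusted p = 0.891 with an estimated correlation), with a median of 0.27 over 17 members. Pair 1 carried this, with a median of 0.63 against −0.08 in pair 2, and 12 members were opposite in the pairs. The list turned down and no longer passed without wild type 1 (adjusted p = 0.515). Zfhx3, a homeobox gene of striatal neurons, had a log2 fold change of 0.64 (SE 0.25), and Isl1, which directs striatal projection neurons, of 0.5 (SE 0.21). Zfhx3 was at 0.34 without knockout 1, and Isl1 at 0.27 without wild type 1. Interneuron genes rose by a median of 0.21 over 18 members (adjusted p = 0.00289; adjusted p = 0.891 with an estimated correlation), with 9 higher and 1 lower in both pairs. The call was lost without knockout 2 (adjusted p = 0.457) and without wild type 1 (adjusted p = 0.813). Gad1, which makes GABA, had 85.1 and 106.3 CPM in wild type 1 and 2, and 119.1 and 123.4 CPM in knockout 1 and 2 (log2 fold change 0.34, SE 0.16, or 0.21 without wild type 1). Nkx2-1, the regulator of the medial ganglionic eminence, had 3.99 and 19.3 CPM in wild type 1 and 2, and 13.3 and 39.9 CPM in knockout 1 and 2. Its log2 fold change of 1.19 (SE 0.73) was 1.78 without knockout 1, 0.19 without knockout 2, 0.48 without wild type 1 and 2.73 without wild type 2. Meningeal fibroblast genes rose by a median of 0.18 over 12 members (adjusted p = 0.00166; adjusted p = 0.891 with an estimated correlation). Their pair medians were 0.65 and −0.14, and 8 members were opposite. Wild type 2, the library richest in epidermal transcripts (284.5 CPM summed over a list chosen after the data were seen, 38.2 to 47.4 CPM in the others), also had the most reads of the collagen genes Col1a1 (247, against 49 to 131) and Col1a2 (222, against 83 to 203). The list turned down without knockout 1 (adjusted p = 0.964), and also lost its call without wild type 1 (adjusted p = 0.477). Zic1 was its 1 member called adjusted over the list alone (adjusted p = 0.0296). The prostaglandin synthase gene Ptgds had a log2 fold change of 0.63 (SE 0.29). Of the striatal and interneuron lists, 0 members were called adjusted over the list alone.

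Intermediate progenitor genes fell (limma camera, adjusted p = 0.000119; adjusted p = 0.642 with an estimated correlation), by a median of −0.25 over 15 members, 11 of them lower in both pairs and 1 higher in both. The call was lost without wild type 1 (adjusted p = 0.0988). Eomes, the T-box factor that defines these cells, had 145.8 ± 9.57 CPM in wild type and 117.3 ± 8.88 CPM in the knockout (SD, n = 2; log2 fold change −0.31, SE 0.14). Neurog2, the proneural factor that starts their neuronal programme, had 139 and 119.6 CPM in wild type 1 and 2, and 82.6 and 109.4 CPM in knockout 1 and 2 (log2 fold change −0.43, SE 0.18, or −0.24 without knockout 1). Radial glia genes fell by a median of −0.1 over 20 members (adjusted p = 0.0213; adjusted p = 0.891 with an estimated correlation), but their pair medians were −0.31 and 0.1 and 10 members were opposite. The list turned up without knockout 1 (adjusted p = 0.964) and also lost its call without wild type 1 (adjusted p = 0.891). The intermediate-filament gene Nes had a log2 fold change of −0.26 (SE 0.13), and the dorsal patterning genes Emx1 and Emx2 of −0.36 (SE 0.19) and −0.28 (SE 0.18), which were −0.15 and −0.1 without knockout 1 and −0.6 and −0.48 without knockout 2. Both progenitor lists had 0 members called adjusted over the list alone.

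Wnt ligands and receptors fell by a median of −0.18 over 25 members (adjusted p = 0.0297; adjusted p = 0.642 with an estimated correlation), 10 lower in both pairs, 4 higher in both and 11 opposite. The call was lost without knockout 1 (adjusted p = 0.568), without wild type 1 (0.477), without wild type 2 (0.121) and after a GC correction chosen after the data were seen (0.178). Wnt9a had 2.55 and 2.9 CPM in wild type 1 and 2, and 1.66 and 1.28 CPM in knockout 1 and 2 (log2 fold change −0.89, SE 0.32). Wnt8b, a ligand of the cortical hem, had a log2 fold change of −0.98 (SE 0.38) that was −0.53 without knockout 1 and −1.64 without knockout 2. No member was called adjusted over the list alone. Wnt/beta-catenin targets did not pass (adjusted p = 0.878), with a median of 0.02 and a mean of 0.03 over 20 members while the test pointed down. The feedback genes Rnf43 and Lef1 had log2 fold changes of −0.7 (SE 0.38) and 0.38 (SE 0.25), and Lef1 was at 0.14 without knockout 1.

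Erythroid genes fell (limma camera, adjusted p = 5.77e-08; adjusted p = 0.642 with an estimated correlation), by a median of −0.26 over 10 members, 6 lower in both pairs and 1 higher in both. The direction held without each library in turn. Hbb-bt was the only member called adjusted over the list alone (adjusted p = 0.00105). When Hbb-bt was left out, a choice made after the data were seen, the median was −0.21 over 9 members and the list still passed (adjusted p = 0.00471). The alpha-globin gene Hba-a1 had 165.9 and 133.9 CPM in wild type 1 and 2, and 119.3 and 121.9 CPM in knockout 1 and 2 (log2 fold change −0.31, SE 0.16). The red-cell membrane genes Slc4a1 and Gypa had log2 fold changes of −0.87 (SE 0.41) and −0.9 (SE 0.43). Without wild type 1 the values of Hba-a1, Slc4a1 and Gypa were −0.13, −0.39 and −0.46.

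**Figure D2:**
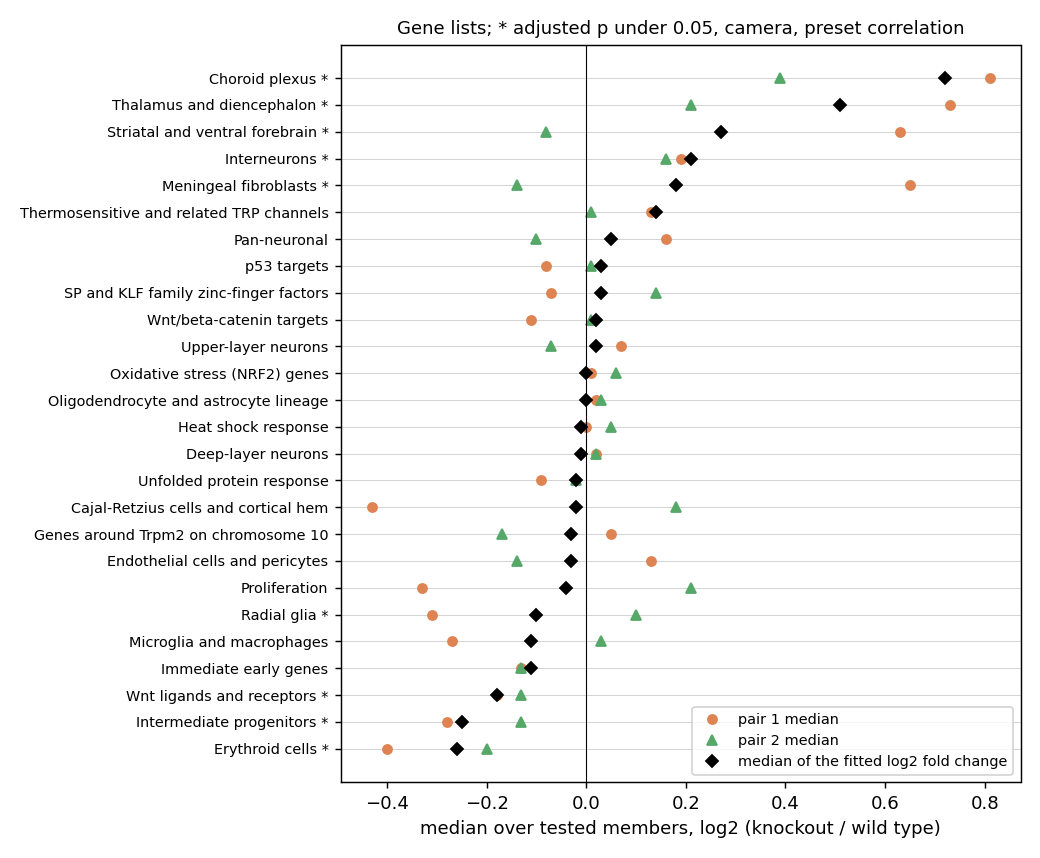
Median log2 ratio of knockout over wild type over the tested members of each of 26 gene lists, in pair 1 (circles), pair 2 (triangles) and the fit to all 4 libraries (diamonds), with a star for an adjusted p under 0.05 by camera at the preset correlation. Choroid plexus (0.81 and 0.39) and thalamic markers (0.73 and 0.21) lay on the higher side in both pairs, while striatal markers (0.63 and −0.08) and radial glia genes (−0.31 and 0.1) differed in sign between the pairs.

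Gene programmes of the response to heat and cell stress did not differ between the genotypes by these tests. Heat shock genes had a median log2 fold change of −0.01 over 23 members (limma camera, adjusted p = 0.707), with 5 higher in both pairs, 4 lower in both and 14 opposite. The small chaperone gene Hspb1 had the widest difference, with 5.64 CPM in wild type 2 and at most 1.12 CPM in the other libraries. Its log2 fold change of −1.94 (SE 1.01) was 0.71 without wild type 2 and −2.72 without knockout 2. The co-chaperone Fkbp4 had −0.18 (SE 0.14), or −0.09 without wild type 2. Oxidative stress genes controlled by NRF2 did not pass (adjusted p = 0.386), with a median of 0 and a mean of 0.15 over 15 members and a test pointing up. The cystine transporter gene Slc7a11 had 1.24 (SE 0.44), and Nqo1, which encodes a quinone reductase, had 0.73 (SE 0.45). Slc7a11 was at 0.61 without knockout 1, and Nqo1 at 0.25 without knockout 2 and 0.48 without wild type 1. The unfolded protein response had a median of −0.02 over 14 members (adjusted p = 0.618), with Creld2 at −0.23 (SE 0.16). The p53 targets had a median of 0.03 over 14 members (adjusted p = 0.895), with Perp at −0.47 (SE 0.4), or 0.14 without wild type 2. Perp is also an epidermal gene, and both Perp and Hspb1 were highest in wild type 2, the library with the most epidermal transcripts (284.5 CPM in sum). Immediate early genes, which report recent cell activity, had a median of −0.11 over 14 members (adjusted p = 0.427), with Ier3 at 0.92 (SE 0.4, or 0.6 without wild type 1) and Fos at −0.72 (SE 0.44), or −0.38 without wild type 2. TRP channel genes had a median of 0.14 over 10 members (adjusted p = 0.288), with the heat-gated channel gene Trpm3 at 0.59 (SE 0.24), or 0.31 without knockout 1. SP and KLF factors, the family of Sp5, had a median of 0.03 over 16 members (adjusted p = 0.871), with Klf6 at 0.32 (SE 0.18), or 0.17 without knockout 1 and without wild type 2. None of these lists had a member called adjusted over the list alone.

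The proliferation, pan-neuronal, cortical layer, Cajal-Retzius, vascular, microglial and glial lists did not pass the threshold either. Proliferation genes had a median of −0.04 over 28 members (limma camera, adjusted p = 0.534), but the pair medians were −0.33 and 0.21 and 23 members were opposite. They passed upward without knockout 1 (adjusted p = 0.0363), and downward without knockout 2 (0.0118) and without wild type 2 (0.000394). The kinetochore motor gene Cenpe had a log2 fold change of 0.3 (SE 0.25), or −0.01 without wild type 2. Pan-neuronal genes had a median of 0.05 over 18 members (adjusted p = 0.534) and passed upward without knockout 2 (adjusted p = 0.0242). The neurofilament gene Nefl had 0.58 (SE 0.26), or 0.12 without knockout 1 and 0.92 without knockout 2. Deep-layer genes did not pass (adjusted p = 0.895), with a median of −0.01, a mean of 0.02 and a test pointing up over 13 members. Foxp2, a forkhead gene of corticothalamic neurons that is also expressed in the thalamus, had 76.9 CPM in knockout 1 and 35.8 to 43.8 CPM elsewhere, and Fezf2, which specifies subcerebral neurons, had a log2 fold change of −0.26 (SE 0.14). Upper-layer genes had a median of 0.02 over 14 members (adjusted p = 0.895). Cajal-Retzius and cortical hem genes had a median of −0.02 over 15 members (adjusted p = 0.255) and passed downward without knockout 2 (adjusted p = 0.000996). Endothelial and pericyte genes (adjusted p = 0.895, 15 members) had a median of −0.03, a mean of 0.02 and a test pointing up. Microglial genes had a median of −0.11 over 14 members (adjusted p = 0.255), with 0 higher and 6 lower in both pairs, among them the lysosomal gene Cd68 at −0.45 (SE 0.2) and the immune adaptor gene Tyrobp at −0.62 (SE 0.3). Oligodendrocyte and astrocyte genes (adjusted p = 0.769, 14 members) had a median of 0, a mean of 0.05 and a test pointing up, with the astrocyte filament gene Gfap at −0.76 (SE 0.31), or −0.47 without knockout 1. The list of genes around Trpm2 on chromosome 10, which holds Trpm2 itself, had a median of −0.03 over 20 members (adjusted p = 0.255). Of these, 8 were lower in both pairs, Trpm2 among them, and 1 was higher in both. The test of this list pointed down, also without wild type 1, knockout 1 or knockout 2, and it pointed up without wild type 2. The neighbour Icosl, a co-stimulatory ligand gene, had −1.3 (SE 0.48). None of these lists had a member called adjusted over the list alone.

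Of the sex-linked genes, only 1 was tested, so that list had no test. Xist, the RNA that silences an X chromosome, had 24283 and 15241 reads in wild type 1 and 2, and 22012 and 21289 reads in knockout 1 and 2. The Y-linked gene Uty had 1 read in each library. Tsix, the antisense transcript of Xist, had 0 reads in wild type 1 and knockout 1, 2 in wild type 2 and 1 in knockout 2.

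Across genes, the knockout over wild-type ratios of pair 1 and pair 2, which share no library, were nearly unrelated. Genes of the thalamus, choroid plexus and ventral forebrain stood out in pair 1, while Hbb-bt, AC149090.1, Tmem181b-ps and Zic4 lay far from 0 in both. Over 14605 genes with a mean CPM of at least 1, the correlation of the log2 ratios was r = 0.04 (rho = 0.01), and 7177 genes (49.1%, Wilson 95% interval 48.3 to 50) had the same sign in both pairs. Genes are not independent replicates, so no p is given. Ttr had log2 ratios of 3.67 in pair 1 and 1.12 in pair 2, Tcf7l2 of 4.05 and 0.26, Gbx2 of 3.85 and 0.33, and Mrps34 of −2.96 and −0.41. Those of Hbb-bt were −2 and −2.14, of AC149090.1 1.46 and 1.2, of Tmem181b-ps 0.92 and 1.51, and of Zic4 0.73 and 1.61. The ratio in pair 2 also varied with the GC content of the transcript (Spearman rho −0.61 across 13165 protein-coding genes), and that of pair 1 did not (rho 0.01). From the GC-poorest decile of genes (median 39.6%) to the richest (59.9%), the pair 2 median went from 0.3 to −0.18.

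**Figure D3:**
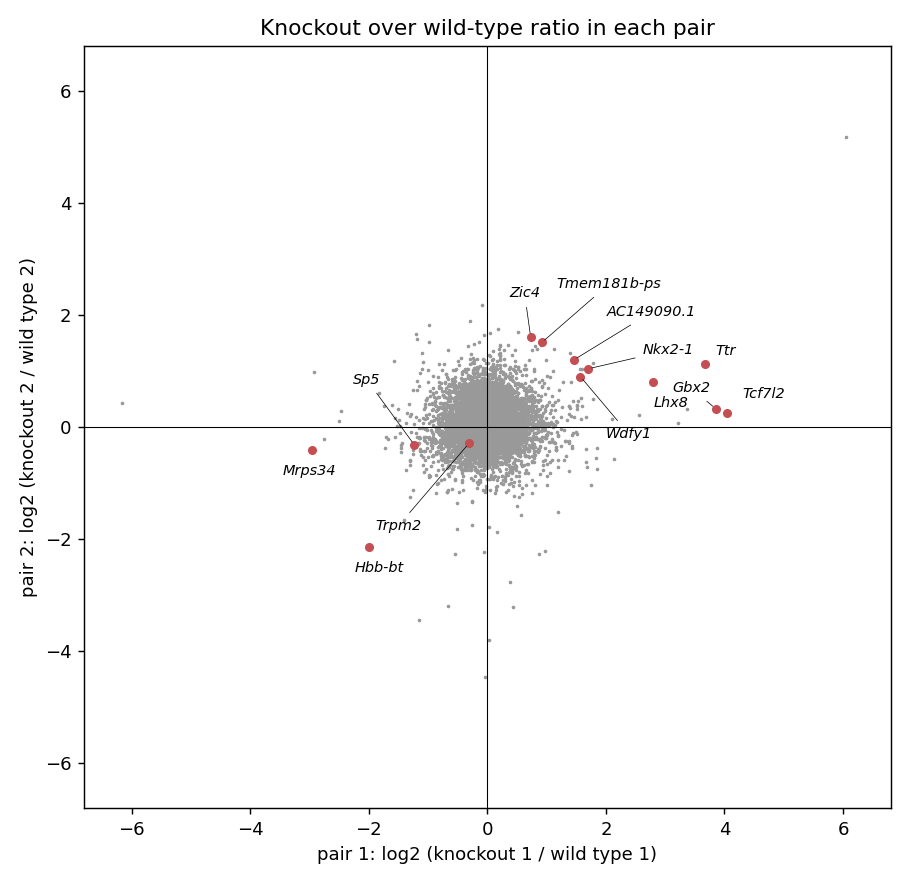
Log2 ratio of knockout over wild type in pair 2 (vertical) against pair 1 (horizontal), with a point for each tested gene with a mean CPM of at least 1 and 13 genes named in red. Tcf7l2 and Gbx2 lay far to the right with pair 2 ratios of 0.26 and 0.33, Hbb-bt was low in both pairs, and the unnamed point at the top right was Gm28438, which had 0 reads in both wild-type libraries.

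**Figure D4:**
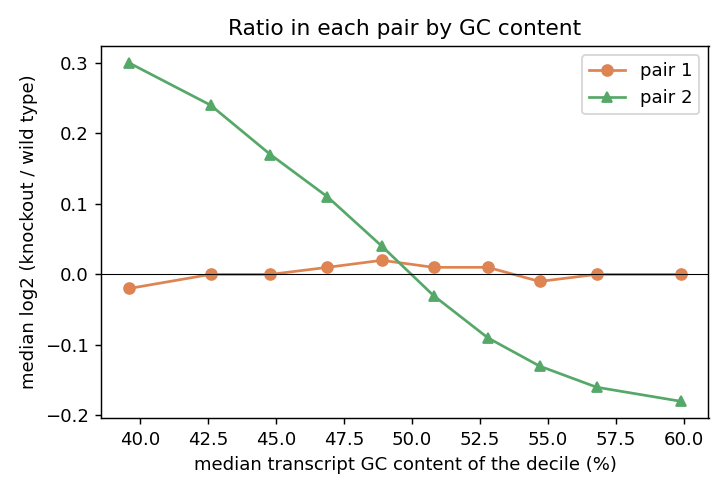
Median log2 ratio of knockout over wild type in pair 1 (circles) and pair 2 (triangles) for genes grouped into 10 bins of equal size by transcript GC content (horizontal, median percent of the bin). Pair 1 stayed between −0.02 and 0.02, and pair 2 went from 0.3 in the GC-poorest bin to −0.18 in the richest.

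The authors' stated threshold, p under 0.05 and an absolute log2 fold change over 1, was applied to their deposited p-values and fold changes. Those p-values compare 1 knockout library with 1 wild-type library, so a call in 1 pair does not measure replication. The resulting calls overlapped more than chance in the same direction and in opposite directions alike, and were mostly separate. Hbb-bt, Nkx2-1 and Ttr were among the genes called in both in the same direction. At this threshold, 878 genes were called in pair 1 and 925 in pair 2. Among genes in both tables, 54 were called in both in the same direction, where 16.2 would be by chance, and 44 were called in opposite directions, where 16.1 would be. Of the 54, 32 were higher in the knockout (9.9 by chance) and 22 were lower (6.2 by chance). With the authors' adjusted p in place of p, the calls numbered 455 and 575, as many as the authors flagged as significant. Of these, 26 were shared in direction (5.6 by chance), with 17 opposite (5.5 by chance). Examples chosen after their values were seen, as log2 fold changes of the authors in pair 1 and pair 2, were Hbb-bt (−2.01 and −2.15), AC149090.1 (1.45 and 1.2), Ttr (3.7 and 1.16) and Nkx2-1 (1.72 and 1.05). Others were the complement regulator Cd59a (1.46 and 1.4), the clotting-factor gene F13a1 (1.93 and 1.29) and the lymphocyte-antigen-family gene Ly6g6e (−1.31 and −1.18). Tcf7l2 (4.07 and 0.26), Syt13 (2.11 and 0.16) and Mrps34 (−3.08 and −0.41) were past the fold threshold in pair 1 only.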

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

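The GC correction, alone or with the replicate block, and the erythroid list without Hbb-bt were chosen after the data were seen. In simulated libraries of the same depth, with the spread between these libraries, the same test recovered 54.5% of genes changed 2-fold. Each simulated gene had the spread typical of its expression level, from which genes in the data can depart, and depth was not varied. The simulated libraries also had no deviation shared by number and no GC trend, unlike the data. The simulation therefore does not tell why the count of edgeR calls was 0.

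The count of 0 genes with edgeR was kept under RLE, upper-quartile and library-size scaling, without a filter, with the CPM filter, without erythroid genes, with limma-voom, with the fold threshold beside the adjusted p and with the GC correction. DESeq2 called 6 genes, and the authors' threshold of unadjusted p and fold gave 92. Without each library in turn the count ranged from 0 to 56. The cause of these differences was not tested.

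Taking the replicate number as a block, which assumes that libraries of the same number are paired, gave 59 genes, 39 higher and 20 lower in the knockout. The replicate block with GC correction gave 14, all among the 59. No label says that a shared number marks a litter or batch. Deviations from the genotype means of libraries of the same number correlated at 0.41 across genes, and the leading principal component (56.3%) placed wild type 1 and knockout 1 at −22.2 and −28 and wild type 2 and knockout 2 at 36.2 and 14.1. With crossed pairs, 36.5% of genes had the same sign.

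Of the gene lists, 9 passed under the alternative scalings and filters, with the block and without Hbb-bt, 8 with the GC correction, alone or with the block, and from 4 to 11 without each library in turn. With an estimated correlation 0 passed, and fry called 0 for a common direction and 0 for any change. camera was not repeated with DESeq2 or limma-voom.

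The log2 fold change of Trpm2 stayed between −0.34 and −0.24 and that of Sp5 between −0.81 and −0.55 in all alternatives that kept the 4 libraries. Over the genes named and these alternatives, 780 values kept their direction and side of the threshold, 36 passed it in the same direction and 0 reversed. Without each library in turn, 303 kept both, 20 passed it and 5 reversed. The ranges with a reversal were −2.81 to 0.71 for Hspb1, −0.88 to 0.14 for Perp, −0.01 to 0.7 for Cenpe and −0.64 to 0.07 for Barhl2, all reversed without wild type 2, and −0.05 to 1.11 for Col3a1, reversed without knockout 1.

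The share of genes with the same sign in both pairs was 48.5% at a mean CPM of at least 10, 49.2% at 0.1 and 50.6% after GC correction of the pair ratios. Calls from the authors' p-values that were shared in direction numbered 26 with their adjusted p. They numbered 133 with the unadjusted p and a fold threshold of 0.5 on the log2 scale (75 by chance). In opposite directions there were 17 and 115 (5.5 and 77.9 by chance). The alternatives for tables of normalized values alone were not run, since counts were given.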

Other observations

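The length test of pair 2 and the chromosome 10 segment and near-identical copy tests of the 195 small-p genes were written down before their results were seen, and the other tests and the epidermal and muscle lists were chosen afterwards.

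Transcripts of the epidermis were seen in the cortex libraries, and mostly in wild type 2. Summed over the list of epidermal genes, the level was 38.2 CPM in wild type 1, 38.9 in knockout 1, 284.5 in wild type 2 and 47.4 in knockout 2, and 20 of 22 members were highest in wild type 2. Wild type 2 had 176 reads of the basal keratin gene Krt5, 256 of its partner Krt14, 275 of the calmodulin-like gene Calm4 and 258 of Krtdap, and wild type 1 and knockout 1 had 0 of each. Lor, which encodes a protein of the cornified envelope, had 871 reads in wild type 2. Skeletal muscle genes, 13 in all, summed to 6.2, 5.4, 10 and 6.3 CPM in wild type 1, knockout 1, wild type 2 and knockout 2.

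Genes of the ventral forebrain varied between libraries of the same genotype. Nkx2-1, the regulator of the medial ganglionic eminence, had 75 and 353 reads in wild type 1 and 2, and 232 and 716 in knockout 1 and 2. The LIM-homeobox gene Lhx8 had 19 and 133 reads in wild type 1 and 2, and 135 and 230 in knockout 1 and 2. Rxrg, a retinoid receptor gene of the striatum, had 165 and 780 reads in wild type 1 and 2, and 559 and 589 in knockout 1 and 2.

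The ratio of pair 2 followed the GC content of the transcript. The loss of Trpm2 was argued against as its source, since the pair 1 ratio had a Spearman rho of 0.01 with GC, and transcript length was too, since the pair 2 rho given length was −0.59. The deviation of wild type 2 from the other 3 libraries had a rho of 0.74 with GC, against −0.55 in wild type 1, −0.49 in knockout 1 and 0.11 in knockout 2. A GC bias of the wild type 2 library may therefore be the source, which stays a hypothesis. How such a bias arose was not tested.

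Thalamic markers were high in knockout 1. The list median lay 0.82 above the wild-type mean there, at percentile 100 of 10000 matched random lists, and at −0.04 in knockout 2 (percentile 21.2), and the median over the 13 members of pair 1 minus pair 2 was 0.64 (95% bootstrap interval over genes, 0.03 to 1.19). These values restate the pattern that drew attention to the list and rest on single libraries, so they decide neither for nor against tissue of another brain region in knockout 1, or an effect of the loss of Trpm2 alike in both knockout libraries, and both stay open. In knockout 1, Tcf7l2 had 103.3 CPM and the abundant Slc17a6 71.5 CPM (65.3 in wild type 1), and 10 of the 13 markers had a mean of at least 1 CPM in the wild-type cortex. Zic4 and Zic1 were higher in both knockout libraries than in either wild-type library.

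The last pattern joins the 195 genes at an unadjusted p under 0.05 and the 6 genes called by DESeq2. For the 195 as a set, an excess from a segment carried with the Trpm2 allele was argued against, with 2 genes within 10 Mb of Trpm2 (median of random sets 3, 95th percentile 6). Many of the 195 may be noise, so single genes of such a segment are not excluded. Icosl, a listed neighbour of Trpm2 with a log2 fold change of −1.3, was among the 195. An excess of near-identical copies was also argued against, with copies found in 27.3% of the 195 and 27.5% of matched genes (Fisher exact p = 1). The genomic background of the knockout line stayed open for the 195, with 23 within 500 kb of another of the same direction (random median 16, 95th percentile 25). For the 6 genes, 4 of the 5 searched had a near-identical copy, against 27.3% of 337 genes matched to them by expression (one-sided Fisher exact p = 0.0232). However, Tmem181b-ps and Dynlt1b lie side by side, and by locus 3 of 4 had one (exact p = 0.0673). Hbb-bt and Gm28438 had 1 copy each, Hbb-bs (edgeR log2 fold change −0.34) and mt-Nd3 (−0.81). Tmem181b-ps and Dynlt1b had 4 copies each, of which Tmem181a (0.65) and Dynlt1c (0.41) are given here and the others are not. Both given copies were themselves among the 195, so they may not be typical of the copies. Among the 195, Tmem181a, Dynlt1b, Tmem181b-ps and Dynlt1c were successive neighbours on chromosome 17 (starts from 6270470 to 6601671), all higher in the knockout. This run was named after its values were seen. That 2 of the 6 lay within 500 kb of each other, a number reached by 0.93% of random sets, had been seen before it was counted and decides nothing, so shared reads, line background and an effect of Trpm2 loss all stay open.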
